A study of Mus musculus with 7 samples.

How the data were processed

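RNA was measured in fluorescently sorted neurons from dissected arcuate nuclei, the part of the ventral hypothalamus that controls feeding, of mouse embryos at E15.5 (embryonic day 15.5). Per the labels, there were 4 libraries of Pomc neurons and 3 of Npy neurons, made from 1 ng of total RNA each with a stranded total RNA kit (SMARTer Stranded Total RNA-Seq v2) and read on an Illumina HiSeq instrument. The reporter that the sort used and the litter or animals behind each replicate are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

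The authors deposited 1 table of 18335 gene symbols with a column for each of the 7 samples. Its header gives no unit. The values deposited by the authors were taken as TPM (transcript abundance, scaled by gene length and to a fixed total per library) from the values themselves. Of the 7 columns, 6 sum to 1000000, and the highest values belong to short RNA genes such as Rpph1. Rpph1 took 5.11 to 6.43% of each Pomc library and 7.11 and 8.57% of the Npy libraries used. All short RNA genes together took 10.8 to 13.1% and 14.1 and 17.3%, so this difference in composition ran with the groups. In genes with a single annotated transcript, TPM times exon length fell on whole multiples of 1 step per library (within 0.05 reads, 10% expected by chance for a fixed step) for 53.4 to 67.1% of the low values of these 6 libraries. Each step was chosen for a high share, so chance can exceed 10%. The column of Npy replicate 3, set aside below, reached 21.3% in the same search. From their steps the 6 libraries used each held about 49.9 to 69.6 times 1000000 reads on genes, an estimate that depends on the exon lengths used. The submitters' processing notes name HISAT2, the mm10 build and edgeR 3.8, with no role or order. The counting tool, the annotation, the use of strand and the length definition are not given in the sources used here. Overlapping genes and genes with near-identical copies, such as the histone genes, are therefore uncertain, and a 0 in the table means only that a gene is listed at 0, since Cox17, a gene of basic respiration, is listed at 0 in Npy replicate 2.

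The column of Npy replicate 3 was not used as a replicate. In all 15223 uniquely named genes with a value in Npy replicate 1 or 2, it equals the mean of those 2 columns multiplied by a whole percent from 95 to 105, within 1e-04 percentage points (largest deviation 1.2e-05). It is 0 in all 3108 genes in which both other columns are 0, and it sums to 996136. In the 60 other sets of 3 columns checked in the same way, at most 0.0072% of the genes met this relation. Neither the labels nor the header mention a calculation, and its reason is not given in the sources used here. The column adds no measurement to the other 2, so the comparison was made between 4 Pomc and 2 Npy libraries. Leaving out this replicate had been planned as an alternative before the data were examined, and the fit on all 7 columns, which had been planned as the main one, is given as an alternative with the planned filter and with the one used here.

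The planned main test needed counts. With TPM, the fallback fixed beforehand was used, which was limma 3.58.1 in R 4.3.3 with a prior variance that follows mean expression (trend), on log2(TPM + 1). A fold change is on this scale, which understates the change of genes with low values. Genes were tested if they reached 1 TPM in at least 2 libraries, the size of the smaller group (the plan, made for 3 Npy libraries, said 3). This left 13845 genes. The 4 rows of 2 date-like symbols that occur more than 1 time were left out. The threshold was an adjusted p (Benjamini-Hochberg) of 0.05, two-sided, and log2 fold changes are Pomc minus Npy with the standard error of the fit. With 4 against 2 libraries there are 15 splits, so an exact permutation test cannot give a p under 0.0667. It was used for the sort markers. No count of calls over other splits was made, because 1 group has fewer than 3 samples.

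The fit was tested on simulated data for 4 Pomc against 2 Npy libraries with 13845 genes. It called 28% of 50 genes with a log2 change of 1, 76% of 50 with 2, 98% of 50 with 3 and 100% of 50 with 4, and 8 of 13645 unchanged genes. The changed genes were drawn among the more highly expressed ones. Simulated gene variances also spread less around their trend than those of the data, so these rates may be too favourable.

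Before the data were examined, 30 gene lists were fixed from general knowledge. They cover anorexigenic and orexigenic neurons, hypothalamic transcription factors, transmitters, neuropeptides, receptors, channels, cell division, histones, ribosomal proteins, respiration, stress, sex and the other cell types that a dissected arcuate nucleus can hold. The 28 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01) and, as alternatives, with an estimated correlation and with fry. Lists overlap: Gad1, Gad2 and Slc32a1 are on both the orexigenic and the GABAergic list, and Pdgfra is on the glial and the fibroblast list. The rule for named genes was fixed too. It takes Pomc, Npy and Agrp, the 10 genes per direction with the largest change among those past the threshold with separate groups, a mean of at least 5 TPM and no clone-like symbol, and of each list up to 4 members past the threshold and up to 2 others with the highest mean. The rule allowed more genes not past the threshold than are described, and those given here were picked from them after their values were seen; 1 gene that the rule allows is withheld and not reported here. Genes named outside the rule are said to be chosen after their values were seen.

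Gene positions come from GENCODE M21 (GRCm38, the same build as mm10), in which 17376 of the 18331 unique symbols were found by name. Alternatives were other pseudocounts (0.1 and 0.5), no filter, stricter filters, a replicate block, robust prior variance, 1 prior variance for all genes, a threshold of 0.01, median-of-ratios and upper quartile scaling, leaving out short RNA genes, and leaving out each library in turn. The replicate block treats same-numbered libraries as pairs. Pomc replicates 3 and 4 have no Npy partner among the libraries used, so its comparison rests on replicates 1 and 2 alone. A call lost under it may therefore reflect the smaller number of libraries.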

Results

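The study compared the transcriptomes of the 2 melanocortin neuron types of the arcuate nucleus during development, with the stated purpose of finding regulators of anorexigenic neuron identity. Pomc neurons make proopiomelanocortin, the precursor of appetite-suppressing peptides, and Npy neurons make neuropeptide Y, which stimulates feeding. Both were sorted from E15.5 mouse hypothalamus, with 4 Pomc libraries and 3 columns for Npy neurons. The column of Npy replicate 3 equals, in all 15223 genes with a value, the mean of Npy replicates 1 and 2 times a whole percent that differs from 100 by at most 5. It is not an independent measurement, so n is 4 for Pomc and 2 for Npy in what follows. Genes above 0 ranged from 12493 in Pomc replicate 4 to 14933 in Npy replicate 1, and Npy replicate 2 had 12922. On log2(TPM + 1), pairs of Pomc libraries correlated across genes at r = 0.85 to 0.92, the pair of Npy libraries at 0.89 and pairs between the groups at 0.82 to 0.92, so the groups overlapped in this measure.

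**Figure D1:**
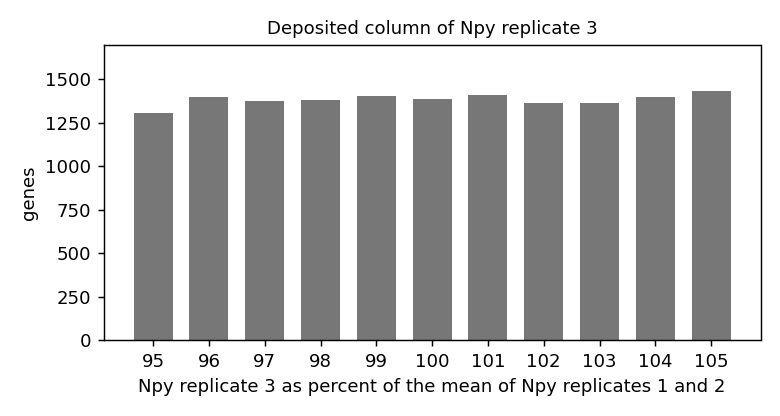
The horizontal axis gives the value of Npy replicate 3 as a percent of the mean of Npy replicates 1 and 2, and the vertical axis the number of genes (15223 in all). Only 11 whole percents occur, none farther than 5 from 100, each in 1306 to 1431 genes.

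The genes used to name the populations differed between them in the labelled direction. Pomc (chromosome 12, 3954951 to 3960642, GRCm38) stood at 518 ± 189 TPM (SD, n = 4) in the Pomc libraries and at 24.0 and 59.4 TPM in the Npy libraries, a log2 fold change of 3.67 ± 0.39 (SE, limma adjusted p = 0.00454; 0.0625 with 1 prior variance for all genes and 0.0667 with a replicate block). Npy (chromosome 6, 49822710 to 49829507) stood at 728 and 513 TPM in the Npy libraries. In the Pomc libraries it reached 152, 2.11, 81.0 and 54.2 TPM, and with this spread its log2 fold change of -3.997 ± 1.249 did not pass the threshold (limma adjusted p = 0.418). Without Pomc replicate 2, the library with the lowest value, it was -2.79 ± 0.40 with an adjusted p of 0.0435. Agrp, the second peptide of adult Npy neurons, was low in both groups, at 0 to 6.82 TPM in the Pomc libraries and at 5.53 and 1.75 TPM in the Npy libraries. The two-sided exact permutation test gave p = 0.0667 for Pomc, the smallest value that 15 splits allow, 0.133 for Npy and 0.667 for Agrp.

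Transcription factor genes were among the genes most strongly higher in Pomc neurons. Nhlh2, a helix-loop-helix factor of hypothalamic neurons, was 35.8-fold higher (126 ± 30.8 TPM against 1.82 and 3.29, log2 5.16 ± 0.34, limma adjusted p = 0.000524). Nr5a1, which encodes steroidogenic factor 1 of the ventromedial hypothalamus (chromosome 2, 38692656 to 38714542), was 27.7-fold higher, at 135 ± 22.9 TPM against 5.25 and 2.81 (log2 4.79 ± 0.30, adjusted p = 0.000524). The zinc finger gene Prdm12 (chromosome 2, 31640037 to 31655795) stood at 199 ± 72.3 TPM against 1.57 and 16.4 (log2 4.84 ± 0.65, adjusted p = 0.0143), and its relative Prdm13 at 63.4 ± 34.4 TPM against 1.40 and 0. Sox14 (log2 5.75 ± 0.57), the LIM homeobox gene Lhx5 (4.54 ± 0.56) and the Wnt effector Tcf7l2 (3.92 ± 0.36) were higher as well. Smaller differences were found for the progenitor factors Sox1 (2.40 ± 0.25) and Sox2 (2.53 ± 0.20) and for Tbx3 (1.20 ± 0.20, adjusted p = 0.0397), which is required for the identity of arcuate neurons. Of the 56 tested hypothalamic transcription factors, 9 were higher in Pomc neurons, 1 was higher in Npy neurons and 46 did not pass; adjusted over the list alone, 13 were higher and 14 lower. Members that did not pass include Otp (498 ± 139 TPM against 771 and 957) and Isl1 (432 ± 45.4 TPM against 637 and 601), which were abundant in both groups. Leaving out a single library ended the calls of Prdm12 (without Pomc replicate 1, 2 or 3, adjusted p up to 0.0562), Lhx5 (without Pomc replicate 1 or 3, up to 0.0523) and Tbx3 (without any 1 of the 6 libraries, 0.0783 to 0.15).

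On the list of anorexigenic neuron genes, 4 of 9 tested members (Nhlh2, Pomc, Prdm12 and Tbx3) were higher in Pomc neurons, and no member was higher in Npy neurons (camera adjusted p = 0.00234; adjusted p = 0.13 with an estimated correlation). The median log2 fold change of the list was only 0.13 and the mean 1.32, and the median turned negative without Pomc replicate 1 (-0.04) or Npy replicate 2 (-0.40). Adjusted over the list alone, the same count was 4, with 1 lower member, Isl1. Pomc names the sorted population, so its direction would follow from the sort. The same holds for Npy on the orexigenic list. Neither list was tested without its sort marker. Of the 8 tested orexigenic neuron genes, none passed the threshold over all genes by limma (6 at an unadjusted p under 0.05), all 8 had log2 fold changes below 0, and 6 were lower in Pomc neurons when adjusted over the list alone (camera adjusted p = 8.83e-08; adjusted p = 0.0532 with an estimated correlation).

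Genes of transmitter use differed as well. Slc17a6, the vesicular glutamate transporter VGLUT2, stood at 60.6 ± 5.04 TPM in Pomc neurons against 5.85 and 1.43 in Npy neurons (log2 3.91 ± 0.45, limma adjusted p = 0.0066). Dlx1, a homeobox gene of GABAergic development, was lower, at 16.6 ± 6.30 TPM against 119.5 and 138.5 (log2 -2.95 ± 0.38, adjusted p = 0.0131). All 11 tested GABAergic neuron genes had log2 fold changes below 0; 1 passed over all genes and 8 passed adjusted over the list alone (camera adjusted p = 1.94e-14; adjusted p = 0.0532 with an estimated correlation). Gad1, which makes GABA, stood at 53.6 ± 11.4 TPM against 165 and 115 (adjusted p = 0.111). The call of Dlx1 ended without Npy replicate 1 or 2, when the Npy group is a single library (adjusted p up to 0.26). The 7 glutamatergic neuron genes as a list were not called (adjusted p = 0.56), with a median of -0.05 and a mean of 0.30. The list was called higher in Pomc neurons with a filter of 5 TPM in at least 3 libraries (median 2.32, adjusted p = 0.000357) and without Npy replicate 1 (1.23, adjusted p = 0.0249). Neurod1 stood at 14.4 ± 5.57 TPM against 7.46 and 0 (adjusted p = 0.564).

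Other peptide genes also differed. Ghrh, which encodes growth hormone-releasing hormone (chromosome 2, 157329497 to 157347506), stood at 96.8 and 112 TPM in the Npy libraries and was listed at 0 in 3 of the 4 Pomc libraries and at 0.296 TPM in Pomc replicate 3 (limma adjusted p = 0.00265). Sst, somatostatin (chromosome 16, 23889573 to 23890958), was abundant in both groups and 5.01-fold higher in Npy neurons, at 2108 and 3187 TPM against 523 ± 93.6 (log2 -2.32 ± 0.23, adjusted p = 0.00345). Adcyap1, which encodes the peptide PACAP, reached 56.1, 55.1, 41.6 and 15.9 TPM in the Pomc libraries and was listed at 0 in both Npy libraries (adjusted p = 0.00749; 0.0504 without Npy replicate 2). Of 19 tested neuropeptide genes, 2 were higher in Pomc neurons (Pomc itself and Adcyap1), 2 in Npy neurons, and 15 did not pass. Adjusted over the list alone, the counts were 2 and 3. The list as a whole was not called (camera adjusted p = 0.398). Among receptors, channels and guidance genes, the cannabinoid receptor gene Cnr1 (log2 2.14 ± 0.21, adjusted p = 0.00345), the calcium channel subunit gene Cacna2d1 (2.94 ± 0.28, 0.00303) and the axon guidance receptor gene Robo2 (2.77 ± 0.44, 0.0351) were higher in Pomc neurons. The call of Robo2 ended without any 1 library except Npy replicate 1 (adjusted p up to 0.12). H2-Ab1, which encodes a chain of MHC class II, reached 39.7, 17.6, 17.5 and 18.6 TPM in the Pomc libraries and was listed at 0 in both Npy libraries (adjusted p = 0.0136; up to 0.106 without Pomc replicate 1, Pomc replicate 3 or Npy replicate 2).

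**Figure D2:**
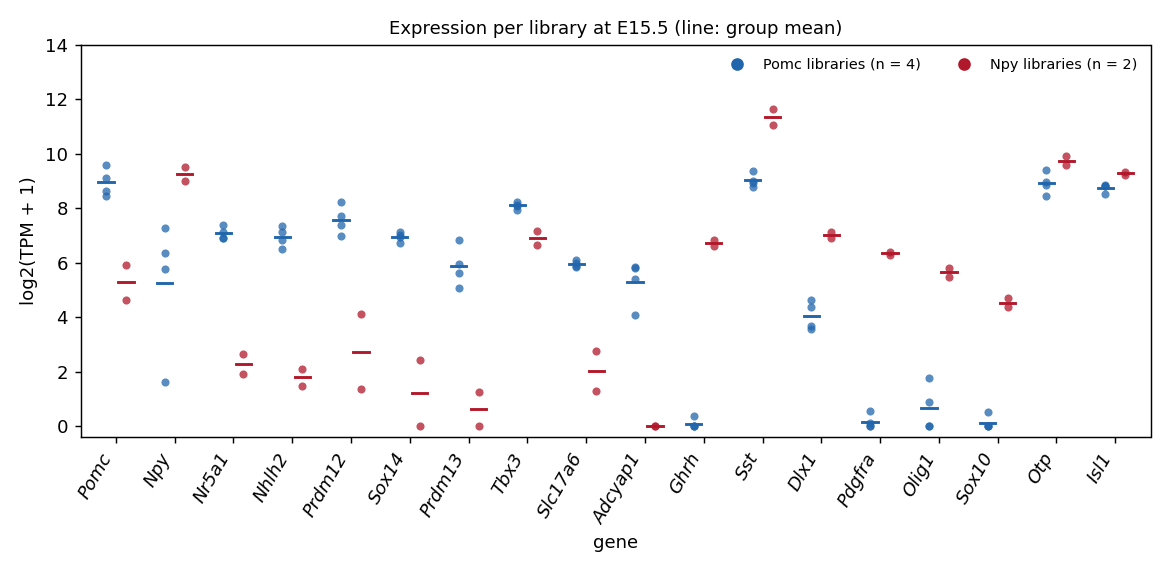
The vertical axis gives log2(TPM + 1) and the horizontal axis 18 genes; each point is a library (blue, 4 Pomc; red, 2 Npy) and the short line is the group mean. Pomc, Nr5a1, Nhlh2 and Prdm12 lie higher in every Pomc library than in both Npy libraries, Ghrh, Sst, Dlx1 and Pdgfra lie lower, and Npy itself spreads from 2.11 to 152 TPM over the Pomc libraries.

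Several genes of oligodendrocyte precursors had values in both Npy libraries and were listed at or near 0 in the Pomc libraries. Pdgfra, the receptor that marks oligodendrocyte precursors (chromosome 5, 75152292 to 75198215), stood at 83.7 and 77.5 TPM in the Npy libraries and at 0, 0.484, 0.0795 and 0 TPM in the Pomc libraries (limma adjusted p = 0.00345). Olig1 stood at 54.8 and 43.9 TPM against at most 2.43, Sox10 at 19.7 and 25.1 TPM against at most 0.444, and Gpr17 at 33.6 and 24.0 TPM against at most 0.222 (adjusted p = 0.0228, 0.021 and 0.0131). Cspg4, at 21.3 and 17.5 TPM, was listed at 0 in all 4 Pomc libraries (adjusted p = 0.0208). Of the 10 tested genes of the astrocyte and oligodendrocyte lineage, 5 were higher in Npy neurons, and 6 when adjusted over the list alone (camera adjusted p = 1.32e-06; adjusted p = 0.0532 with an estimated correlation). Over the list, mean log2(TPM + 1) was 4.20 and 4.16 in the Npy libraries and 1.61 to 1.94 in the Pomc libraries, while the 17 pan-neuronal genes stood at 8.08 and 7.67 against 7.98 to 8.34. Leaving out 1 Pomc library ended the calls of Sox10 and Cspg4 (replicate 1, 2 or 3, adjusted p up to 0.0887), Gpr17 (replicate 1 or 3, up to 0.0591) and Olig1 (replicate 1 or 2). Without Npy replicate 1 or 2, Pdgfra, Gpr17, Sox10 and Cspg4 no longer met the filter, Olig1 was tested and did not pass (up to 0.295), and the list was not called.

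Cell division genes and histone genes were higher in the Npy libraries as lists. Of 26 tested cell cycle genes, 24 had log2 fold changes below 0, none passed over all genes by limma (9 at an unadjusted p under 0.05) and 3 passed adjusted over the list alone (camera adjusted p = 8.83e-08; adjusted p = 0.13 with an estimated correlation). Their mean log2(TPM + 1) was 3.50 and 3.13 in the Npy libraries against 1.64 to 2.56 in the Pomc libraries, and so moved with the oligodendrocyte genes. Of 53 tested histone genes, 42 were below 0, 1 passed and 6 passed adjusted over the list alone (adjusted p = 1.95e-07; adjusted p = 0.229 with an estimated correlation). The member that passed was the linker histone gene Hist1h1b, at 36.3 and 53.6 TPM against 0 to 2.78 (adjusted p = 0.0358; up to 0.558 without Pomc replicate 1, 2 or 3 or either Npy replicate). Pan-neuronal genes (median log2 0.35, adjusted p = 0.0121) and cytosolic ribosomal protein genes (median 0.15, adjusted p = 0.00189) were called higher in Pomc neurons, with no member past the threshold by limma over all genes or adjusted over the list alone and 5 of 17 and 5 of 81 members at an unadjusted p under 0.05. With an estimated correlation their adjusted p were 0.556 and 0.862. The pan-neuronal call ended without Npy replicate 2 (0.186) and the ribosomal call without Pomc replicate 1 or Npy replicate 1 (up to 0.768). Tubb3, a neuronal tubulin gene, stood at 1862 ± 338 TPM against 1094 and 1439 (limma adjusted p = 0.636).

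**Figure D3:**
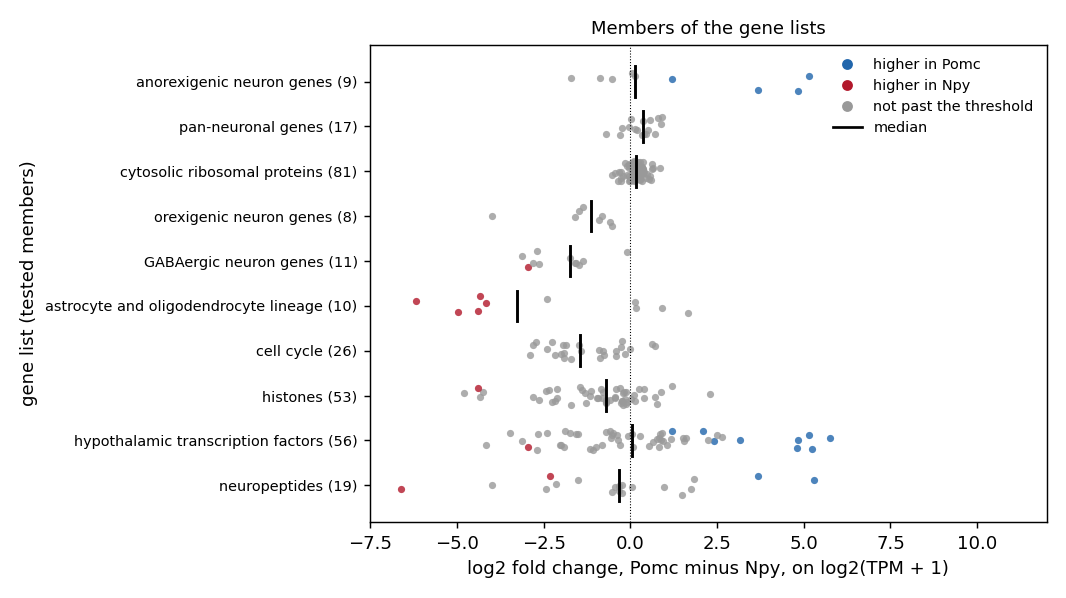
The horizontal axis gives each gene's log2 fold change (Pomc minus Npy, on log2(TPM + 1)) and the vertical axis 10 gene lists with their number of tested members; blue and red points passed the threshold, grey points did not, and the black line is the list median. The GABAergic list has all 11 members below 0, and the astrocyte and oligodendrocyte list has 5 members past the threshold, all higher in Npy neurons.

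The other lists were not called by camera. Their adjusted p were 0.51 for hypothalamic transcription factors, 0.375 for monoamine and acetylcholine genes, 0.934 for peptide processing genes, 0.984 for metabolic and hormone receptors, 0.845 for pituitary cell genes, 0.576 for radial glia and tanycyte genes and for the Notch pathway, and 0.845 for microglia. Endothelial and pericyte genes had 0.204, fibroblast and meningeal genes 0.177, stress and immediate early genes 0.239, axon guidance genes 0.398, potassium channels 0.576, sodium and calcium channels 0.845, GABA and glycine receptors 0.239, glutamate receptors 0.927, oxidative phosphorylation genes 0.845 and sex-linked genes 0.239. Median, mean and test differed in sign for some of these, such as the receptors (median -0.06, mean 0.10, test towards Npy). Camera looks for a shift of a list to 1 side. By fry's mixed test, which takes changes in either direction together, 18 of all 28 lists were called. Among them were hypothalamic transcription factors (fry mixed adjusted p = 7.7e-06) and metabolic and hormone receptors (3.05e-06). Only 2 red blood cell genes reached the filter, and the table holds no mitochondrially encoded genes. The dopamine enzyme gene Th stood at 10.8 ± 6.58 TPM in Pomc neurons against 96.8 and 116 in Npy neurons (limma adjusted p = 0.142), and the radial glia gene Fabp7 at 25.6 ± 25.5 TPM against 323 and 176 (adjusted p = 0.272).

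In all, 57 of 13845 tested genes passed an adjusted p of 0.05 by limma, 40 higher in Pomc and 17 higher in Npy neurons, all with at least a 2-fold difference. In all 57 the groups did not overlap, as in 15.9% of all tested genes, where chance gives 13.3%. At an unadjusted p under 0.05 there were 1019 genes. With Npy replicate 3 counted as a replicate of its own and the same filter the fit tested 14149 genes and called 205 (110 and 95), which included the 57 and still rest on 2 Npy measurements. The count fell to 31, 36 and 29 genes without Pomc replicate 1, 2 or 3. With 1 Npy library left out, genes found only in the Npy libraries miss the filter, so the number higher in Npy neurons is then not comparable.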

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

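In each gene described here and in 5 library measures, the library farthest from the others of the Pomc group was set against the range of the 4 libraries. Of 52 genes and 5 measures, 7 genes stood out, and chance gives about 1 in 20. Mir1897 reached 322 TPM in Pomc replicate 4 against 112 to 136 TPM in the other Pomc libraries. H2-Ab1 reached 39.7 TPM in Pomc replicate 1 against 17.5 to 18.6, and Mrpl21 was at 12.2 TPM in Pomc replicate 4 against 36.7 to 41.4. The other 4 are genes listed at or near 0 in the Pomc libraries, flagged for a low value in a single Pomc library: Ghrh at 0.296 TPM in replicate 3, Pdgfra at 0.484 TPM in replicate 2, Mir7068 at 1.03 TPM in replicate 3 and Sox10 at 0.444 TPM in replicate 4. In Ghrh, Mir7068 and Sox10 the other 3 Pomc libraries are listed at 0, so that any value above 0 is flagged. The chance rate does not apply to these genes, and their flags show nothing about the library.

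The test of a single deviating library in the next paragraph was chosen after the result was seen. It replaced a first version, over the called list members and the further genes, in which 7 of 16 genes lay higher in both Npy libraries than in every Pomc library. By the bound set for it that version had pointed towards a single library. It counted genes outside the list, some of which differ the other way, such as Dll3 and Vcan. Also chosen afterwards was the limit of 20 TPM used there and in the paragraph on the ventromedial nucleus. The other tests were written down before their results.

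Over the 10 tested list members, both Npy libraries lay above every Pomc library. Mean log2(TPM + 1) was 2.23 higher in the lower Npy library than in the highest Pomc library. The range over the Pomc libraries was 0.32. The 2 Npy libraries stood at similar levels, 4.2 and 4.16, which argues against 1 deviating library for these 10 members. Members under 1 TPM in every Pomc library were tested only if both Npy libraries reached 1 TPM. This filter fixed their direction but not their level. Their values had been seen before this test. Oligodendrocyte precursor cells among the sorted Npy cells are a candidate explanation, although the sort would be meant to remove them. In 11 further precursor genes fixed before the test, of which Dll3 and Nkx2-2 are also on other fixed lists, the median log2 fold change was -0.39. This was lower than in all but 3.81% of random lists matched on expression. The median fell short of the -1 set beforehand for such cells and met the bound against them, above -0.5. Members went both ways, with Lhfpl3 and Sulf2 at -2.08 and -1.07 and Dll3 and Vcan at 2.36 and 1.71, none past the threshold. This does not decide, since the median lies within its standard error of 0.50 from the bound of -0.5. In Pomc neurons 5 of the 11 genes stand at 20 TPM or more, where a small share of other cells would not show, and the other 6 have a median of -0.47 ± 0.82 (SE), which decides no more. Expression of these genes by the Npy neurons or their precursors, a difference of neuron type that the design names, was not tested and stays open.

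Nr5a1, Adcyap1 and Slc17a6, higher in the Pomc libraries, are also genes of the neighbouring ventromedial nucleus, and cells of that nucleus among the sorted Pomc cells may contribute to them, although the dissection and the sort would be meant to remove them. In 11 other genes of that nucleus fixed before the test, the median log2 fold change was -0.17, under the bound of 0.5 set beforehand and inside the middle of the random lists. Fezf1, Nr0b1, Nkx2-2 and Slit3 among them are also on the gene lists fixed at the start, and so were tested there too. That bound was badly chosen, because 5 of the genes stand at 20 TPM or more in Npy neurons, and the other 6 have a median of 1.06 ± 0.78 (SE), with Fezf1, Nr0b1 and Rreb1 at 2.64, 2.50 and 1.68, none past the threshold. These members go both ways, so whether such cells are present cannot be told apart from expression in the Pomc neurons themselves, the difference the design names.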

How the results depend on the processing

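The 32 named genes past the threshold kept their direction under every alternative in which they were tested; 484 of 600 values stayed past it and 116 did not. Of 20 named genes not past it, 386 of 398 values stayed so, 11 passed and 1 changed sign. The fit on all 7 columns with 1 TPM in at least 3 libraries had been planned as the main one of the fallback. The alternatives with all 7 columns and the filter used here, 1 TPM in at least 3 libraries, both other scalings, no short RNA genes and 1 prior variance for all genes were added after seeing the data. Of 57 genes past the threshold (40 higher in Pomc, 17 in Npy), a pseudocount of 0.1 left 37 (8 in Npy), no filter 33 (22 and 11) and a threshold of 0.01 24 (18 and 6), all at least 2-fold. Short RNA genes took more of the Npy libraries. With these genes left out and the rest rescaled, 62 passed (44 and 18), 52 of them among the 57. Requiring 5 TPM in at least 3 libraries gave 5 genes higher in Npy, and 1 TPM in at least 3 libraries 8, since genes found only in the 2 Npy libraries are then not tested. For the same reason the median of the astrocyte and oligodendrocyte list was 0.54 (adjusted p = 0.632; 8.51e-07 to 0.747 over its alternatives) with the 5 TPM filter. With 1 prior variance, 21 genes were higher in Pomc of 42 in all (29 of them among the 57), a share of 50% against 70.2%; the cause was not tested. It ended the calls of 9 of the 32 named genes, among them Pomc (log2 3.67 ± 0.49, SE, against 3.67 ± 0.39; adjusted p = 0.0625), Sst, Sox1 and Dlx1.

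With all 7 columns, 205 genes passed (110 in Pomc, 95 in Npy), 179 of them at least 2-fold; with 1 TPM in at least 3 libraries as well, 199 (110 and 89), 174 of them at least 2-fold. The replicate block, which compares only replicates 1 and 2, gave 12 genes (10 and 2, all at least 2-fold), 10 of them among the 57. On these fewer libraries it ended the calls of 25 of the 32 named genes, Pomc included (log2 3.75 ± 0.52, limma adjusted p = 0.0667). Same-numbered libraries deviated from their group means with r = -0.04 and -0.03. With 2 Npy libraries these deviations mirror each other and cannot show a shared litter or batch.

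Without each library in turn, 22 to 69 genes passed, also at 2-fold, 20 to 68 in Pomc and 1 to 19 in Npy. Without an Npy library, the lone one is assumed to vary like the Pomc libraries. Agrp, not past the threshold, ranged from -1.15 to 0.095 (without Npy replicate 1). Of 24 named genes tested in all 6 of these fits, 14 passed in each. The lists called numbered 7 to 10 under all alternatives by camera's preset correlation, and none with an estimated correlation except 3 with all 7 columns. By fry's directional test 6 lists were called, 5 of them among the 8 that camera called in the main fit. Histones, pan-neuronal and ribosomal genes were not called by it (fry adjusted p = 0.221, 0.325 and 0.693), and fibroblast and meningeal genes were (0.00311). In that last list of 6 tested genes, the only member past the threshold was Pdgfra (log2 -6.18), which is also on the glial list. Its median was -0.19 and its mean -1.01, so the call rests largely on this gene. Of 20 lists not called, 8 were called by the preset in at least 1 alternative. The median of the anorexigenic list ranged from -0.402 to 2.435, still called higher in Pomc. Count-based tests and normalizations listed beforehand were not run, since the table holds no counts. Without counts, the counting error of each gene is unknown.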

Other observations

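Overlapping genes at the Sox2 locus were higher in Pomc neurons together. Sox2 (chromosome 3, 34650405 to 34652461) lies inside the long noncoding gene Sox2ot (34104270 to 34682619) on the same strand, and Mir1897 (34638464 to 34638542) overlaps an exon of Sox2ot. Sox2ot, chosen after its values were seen, stood at 169.5 ± 34.3 TPM in Pomc neurons against 21.1 and 16.0 TPM in Npy neurons (log2 3.12 ± 0.25, limma adjusted p = 0.0017). Sox2 stood at 242 ± 36.9 TPM against 39.3 and 42.5, and Mir1897 at 112 to 322 TPM against 5.21 and 0. How reads were divided between these overlapping genes is not given in the sources used here.

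The 4 microRNA genes among those higher in Npy neurons lie inside protein-coding genes that did not pass the threshold. Mir6976, Mir6984 and Mir6402 were listed at 0 in all 4 Pomc libraries and stood at 36.6 and 244, 56.6 and 116, and 58.6 and 29.99 TPM in the Npy libraries. They lie in introns of Srf, Mrpl21 and Elavl2 (chosen, like Cherp, after the microRNA values were seen), whose log2 fold changes were -0.66, -0.41 and -0.70 (limma adjusted p = 0.791, 0.888 and 0.808). Mir7068, at 15.6 and 41.7 TPM in the Npy libraries, overlaps an exon of Cherp (log2 -0.08, adjusted p = 0.952). These genes are 63 to 80 nt long, so that few reads give a high TPM, and a total RNA library of this kind does not separate microRNA precursors from intron reads.

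Genes that differ between the sexes varied from library to library. Xist, expressed from the inactive X chromosome, stood at 358 TPM in Npy replicate 1 and 17.8 in Npy replicate 2, and at 38.3, 107, 0 and 211 TPM in Pomc replicates 1, 2, 3 and 4. The Y-linked gene Ddx3y stood at 1.76 and 25.3 TPM in the Npy libraries and at 14.95 to 44.99 TPM in the Pomc libraries. Of 6 tested sex-linked genes, 4 had log2 fold changes above 0 and 2 below (median 1.805). The list was not called in the main fit (camera adjusted p = 0.239). It was called in some alternatives, such as 5 TPM in at least 3 libraries (camera adjusted p = 0.0252). The fit did not adjust for sex.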
